A study of Mus musculus with 12 samples.

How the data were processed

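RNA sequencing libraries were made from the frontal cortex of C57BL/6 mice, 7 wild-type (WT 1 to 7) and 5 Upf3b-null (KO 1 to 4 and KO 6), with groups and numbers taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol and a column kit and checked on a TapeStation before Illumina library preparation. The deposited values are whole-number read counts per RefSeq gene and library, neither normalized nor pooled. STAR and the mm10 build are named, per the submitters' processing notes, without a version of STAR. The counter, its strand setting, the handling of duplicate reads and any filter on genes are not given in the sources used here. Counts of overlapping or antisense genes and of close paralogs are therefore uncertain, since reads from one may be counted for the other.

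The counts of the most abundant genes hardly followed the library total. Camk2a ran from 3543 to 3817 counts over the 12 libraries, a ratio of 1.08, while the highest library total was 1.41 times the lowest. Counts that level off in this way understate changes of densely counted genes and can shift them between libraries of unequal depth. The highest count per exonic base of any gene in any library was 1.73. Library totals ran from 4684040 to 6617760 counts, and the 10 most abundant genes took at most 1.02% of a library.

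Of the 14909 genes 14438 were matched to GENCODE M21, which uses the same build, by symbol and 405 by RefSeq accession, and 66 were not matched. There were 23 symbols that a spreadsheet had turned into dates, and these were renamed from their accessions. Exonic lengths came from the RefSeq transcripts paired with each gene, and 14219 tested genes had one.

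Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr by group, a quasi-likelihood fit with group as the only term, all 12 libraries and Benjamini-Hochberg adjustment at 0.05. CPM values use TMM-scaled library sizes. Fold changes are KO over WT on the log2 scale with their SE. The level of Upf3b was also compared with an exact two-sided permutation test of log2 CPM with a pseudocount of 0.5 CPM. List levels were compared in the same way, with a pseudocount of 0.5 counts. Gene lists were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, for lists with at least 5 tested genes, with Upf3b removed, and again with an estimated correlation and with fry. Of 33 lists 30 could be tested: 1 was called higher and 8 lower with the preset correlation, 0 with an estimated correlation (smallest adjusted p 0.320) and 12 by fry, which asks whether a list's own genes move and compares them with no others. With density offsets 6 were called, 5 of them in both fits.

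The 33 lists covered NMD factors, the exon junction complex, reported NMD substrates, snoRNA hosts, splicing regulators with poison exons, stress responses, immediate early genes, glucocorticoid response, the circadian clock, progenitors, immature neurons, excitatory and inhibitory synapses, X-linked intellectual disability, neuronal, glial, vascular, choroid plexus and blood cell types, striatum, olfactory bulb, hippocampus and thalamus, interferon response, mitochondrially encoded mRNAs, oxidative phosphorylation, ribosomal proteins, heat shock and sex-linked genes. Several genes sit in more than 1 list, and many neighbouring-tissue markers are also expressed in cortex. Blood cell, mitochondrially encoded and sex-linked lists had too few tested genes for camera. Genes with a stop codon over 50 nt upstream of the last exon junction in any annotated transcript were compared with all others by camera, and calls within 10 Mb of Upf3b with calls elsewhere by Fisher's exact test, and, after the data were seen, lower calls alone in the same way and all tested genes there by camera.

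The groups, tests, lists, the rule for named genes and the first set of other settings were fixed before the data were examined. That rule names Upf3b; the 12 higher and 12 lower genes with the largest fold changes among those that pass, have a mean log2 CPM of at least 1 and keep their sign without any 1 library; up to 4 passing members of each list by smallest p, and 2 members where none passes or as values that do not pass; and up to 6 passing genes near Upf3b. Other genes named were chosen after their values were seen, and this is said where they appear. Some genes that the rule names are not reported here.

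The settings chosen beforehand were DESeq2 size factors and upper-quartile factors, the Wald test of DESeq2 1.42.0, limma-voom with and without sample weights, no filter and a filter of 1 CPM in 5 libraries, the mouse number as a block, each library left out, robust dispersion, 1 surrogate variable from sva 3.50.0, other thresholds, other windows and another definition of NMD features. Settings chosen after seeing the data were offsets for count density, cyclic loess with 3 iterations, the log2 library total as a covariate, and leaving out KO 2 and WT 4. On the first principal component (36.0% of the variance) KO 2 lay at 36.7, against 2.86 to 15.5 in the other KO libraries. WT 4 lay at 9.04, inside that KO range and apart from the other WT libraries (-24.6 to -6.75). Density offsets came from a loess curve with a span of 0.3, fitted in each library to deviations of log2 CPM against the log2 mean count per exonic base.

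The steps were tested on simulated counts drawn from the means and sizes of these libraries. With 200 changed genes among 14210 tested in the comparison of KO with WT, edgeR recovered 42% of those changed 1.25-fold, 80% at 1.5-fold, 92% at 2-fold and 98% at 4-fold, with 6 false calls. With density offsets, on 14162 genes, it recovered 30%, 86%, 88% and 100%, with 8 false calls. Where only a density trend and no gene change was simulated, on 14157 genes, edgeR without offsets made 1031 calls and with offsets 0. That trend was taken from the same density curves that the offsets fit, so the 0 was built in. No trend with exonic length was simulated, so this does not show how well the offsets limit false calls in the real data. Camera found the 1 list that was moved and called 0 others. Genes were drawn independently in these simulations, so they do not test camera where the genes of a list vary together.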

Results

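Bulk RNA sequencing was used to compare frontal cortex from wild-type C57BL/6 mice with that from mice lacking Upf3b, an X-linked gene. Its protein takes part in nonsense-mediated mRNA decay (NMD), the pathway that degrades transcripts carrying premature stop codons. The question was which genes are expressed at different levels in the frontal cortex when Upf3b is absent. There were 7 wild-type (WT) and 5 knockout (KO) libraries, 1 per mouse. The deposited table held whole-number counts for 14909 genes, and 14274 of them had enough counts to be tested. Total counts per library ran from 4684040 to 5425770 in WT and from 4990640 to 6617760 in KO, so most KO libraries were deeper. The biological coefficient of variation was 8.11%. WT 6 and WT 7 were the closest pair (chi-square per degree of freedom 1.02, against 1.19 to 6.98 in other pairs), but their counts still differed, as in 9 against 56 for Ttr, and they were kept as 2 libraries.

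Upf3b was nearly lost from every KO library. It lies on chromosome X at 37091678 to 37110322 of the mm10 build, on the minus strand. The 7 WT libraries held 157 to 219 counts and the 5 KO libraries held 11 to 24. The level was 38.3 ± 2.48 CPM in WT (SD, n = 7) and 2.76 ± 0.877 in KO (SD, n = 5), or 7.20% of WT. The log2 fold change was -3.78 ± 0.13 (SE), with an edgeR quasi-likelihood adjusted p of 7.21e-11. An exact two-sided permutation test over the 792 arrangements of the libraries gave p = 0.00253, the smallest it can give. No library went against its label.

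**Figure D1:**
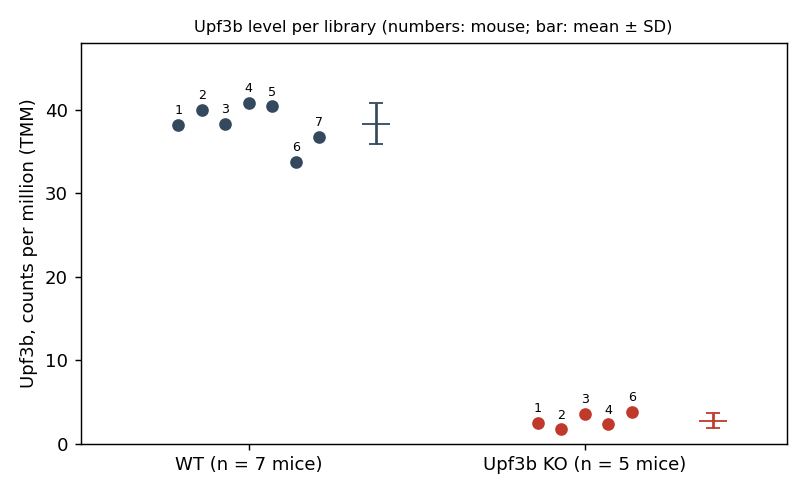
Upf3b in CPM (vertical axis) for each of the 7 WT and 5 KO libraries. Points are mice, numbered as in the labels, and bars show the group mean ± SD; the KO mean is 2.76 and the WT mean 38.3.

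Many genes differed between the groups, mostly by small amounts. With edgeR's quasi-likelihood test 2183 genes were higher in KO and 2050 were lower at an adjusted p under 0.05, but only 67 of the higher and 13 of the lower ones changed by 2-fold or more. The largest rise was in Gdpd3, a lysophospholipase D, which went from 0.551 ± 0.320 to 7.38 ± 2.37 CPM (log2 fold change 3.68 ± 0.31 SE, adjusted p = 5.85e-06). Rmst, a long noncoding RNA of the developing brain, rose by a log2 fold change of 2.64 ± 0.25, and Angptl7, a secreted angiopoietin-like protein, by 2.54 ± 0.24. Cwh43 rose from 7.93 ± 1.06 to 26.7 ± 4.34 CPM and Wdfy1, an endosomal FYVE-domain protein, from 34.1 ± 1.88 to 96.6 ± 6.13 CPM, with log2 fold changes of 1.74 ± 0.12 and 1.51 ± 0.05. The other genes among the 12 with the largest rises were Psmc3ip, Slc5a11, Gbp11, Rgs22, Alpk1, Ttc39aos1 and Serpina3g, with log2 fold changes of at most 2.13. Psmc3ip in KO 4 (4.31 CPM), Gbp11 in KO 6 (1.81 CPM) and Serpina3g in KO 3 (1.92 CPM) lay inside the WT range, apart from the other KO mice. The substrain and colony of the C57BL/6 mice are not given in the sources used here. Background variants can therefore not be told apart from the loss of Upf3b at single genes such as these.

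Among the 12 largest falls, Cort, which encodes the interneuron neuropeptide cortistatin, dropped from 13.2 ± 1.87 to 5.54 ± 0.511 CPM (log2 fold change -1.25 ± 0.13 SE, edgeR adjusted p = 2.53e-05). Spp1 (osteopontin) fell from 13.1 ± 1.78 to 5.68 ± 3.35 CPM, Gpnmb from 5.16 ± 1.33 to 2.38 ± 0.713 CPM, and Etnppl, a phospholyase of astrocytes, from 35.8 ± 7.84 to 16.4 ± 6.74 CPM. The keratin genes Krt12 and Krt20, 1700034G24Rik, Nat8f5, 4931408D14Rik, Inmt, 4930412C18Rik and Vill had log2 fold changes between -1.69 and -0.96. In Krt12 the fall was seen in 4 of the 5 KO mice, at 3.89 to 7.10 CPM. KO 6 lay at 45.9 CPM, inside the WT range of 31.7 to 46.2. Krt20 in KO 6, 4931408D14Rik in KO 1 and Inmt in KO 3 also lay inside the WT range, apart from the other KO mice. Of the 24 genes with the largest changes, 19 passed in every fit that left out 1 library. The exceptions were Krt12, Krt20, Inmt, Vill and 4931408D14Rik, whose highest adjusted p values in those fits were 0.0536, 0.111, 0.0863, 0.0970 and 0.0504. With the library total as a covariate 18 of the 24 lost the call, including all 12 falls, with SEs 1.41 to 1.98 times as large. All 24 kept their direction, and 9 of the 18 had a log2 fold change at least as large as before, such as Spp1 (-1.17 to -2.07), while that of 4931408D14Rik shrank most (-1.61 to -0.71).

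**Figure D2:**
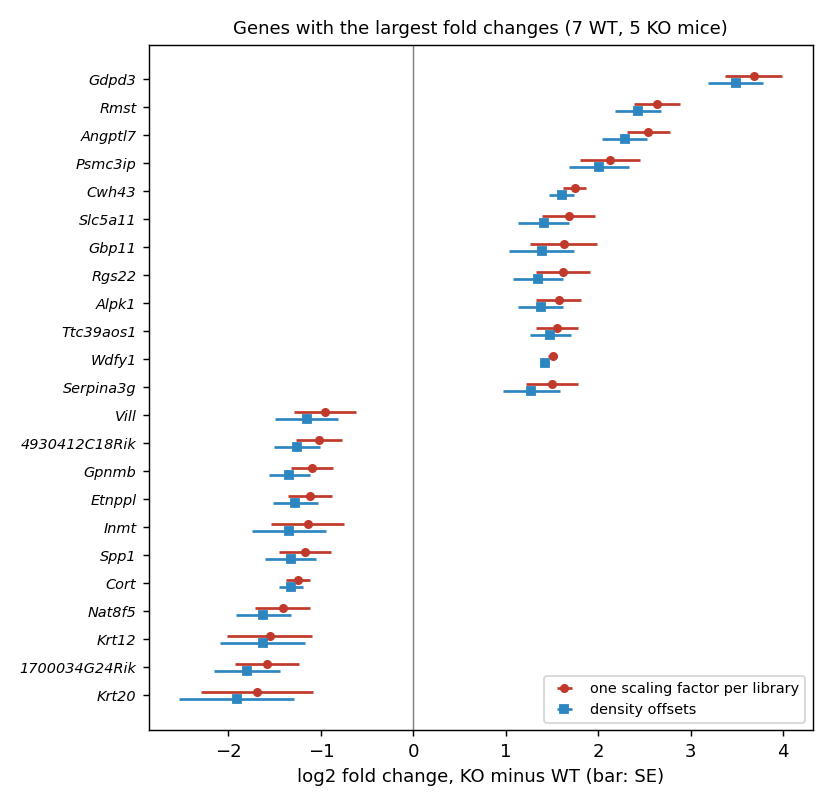
Log2 fold change, KO minus WT (horizontal axis), of 23 of the 24 genes with the largest changes; 4931408D14Rik has no annotated length and is left out. Circles are fits with 1 scaling factor per library, squares fits with offsets for count density, and bars are SEs; all 23 genes keep their direction in both.

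Fold changes depended on how densely a gene was counted, and this limits the number of genes that can be called. With genes split into 10 bins of rising count per exonic base, the median log2 fold change ran from 0.25 in the lowest bin to -0.18 in the highest. With offsets that remove this trend in each library, a choice made after seeing the data, 1175 genes were higher and 1175 lower. These offsets left a trend with exonic length, with a Spearman rho across genes of 0.292 before and 0.240 after. The 2 fits shared 927 higher and 822 lower genes. Of the genes called lower without offsets 278 had the opposite sign with them, against 3 of those called higher. Of 67 genes taken by the naming rule from the lists or near Upf3b that passed in both, 24 had a log2 fold change over 1.5 times smaller with these offsets and none over 1.5 times larger. With the log2 library total in the fit as a covariate, 84 genes were higher and 11 lower (88.4% higher, against 51.6%), and 90 genes passed in all 3 fits in 1 direction.

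**Figure D3:**
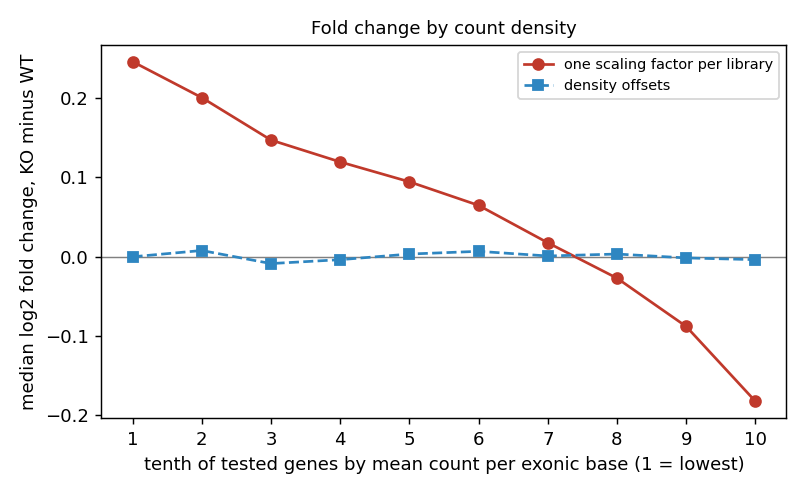
Median log2 fold change, KO minus WT (vertical axis), in 10 bins of the tested genes by mean count per exonic base (horizontal axis, lowest first). With 1 scaling factor per library (circles) the median runs from 0.25 to -0.18; with density offsets (squares) it stays near 0.

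The genes of the NMD machinery itself were higher in KO. Of the 17 tested members other than Upf3b, 8 rose and none fell, with the same 8 adjusted over the list alone. Dhx34, an RNA helicase, rose by a log2 fold change of 0.38 ± 0.06 (SE), Mov10, a helicase that binds Upf1, by 0.75 ± 0.14, and the endonuclease Smg6 by 0.19 ± 0.04. The list as a whole was higher than other genes by camera, a competitive gene set test (adjusted p = 0.0238 over 30 lists; adjusted p = 0.320 with an estimated correlation). With density offsets 6 of the 17 rose (camera adjusted p = 0.00619; 0.168 with an estimated correlation), and the mean level was 0.075 ± 0.029 in KO against -0.053 ± 0.020 in WT on the log2 scale (SD), with no overlap between the 5 KO and 7 WT libraries (exact two-sided permutation p = 0.00253, the smallest possible). Each list level tested by permutation gave the same p, and these p values were not adjusted over lists. Without density offsets 10.6% of single tested genes also separated KO from WT without overlap, against 0.253% by chance. The camera call was lost without WT 4 (adjusted p = 0.0538), without both KO 2 and WT 4 (0.0508) and with the library total as a covariate (0.0938).

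**Figure D4:**
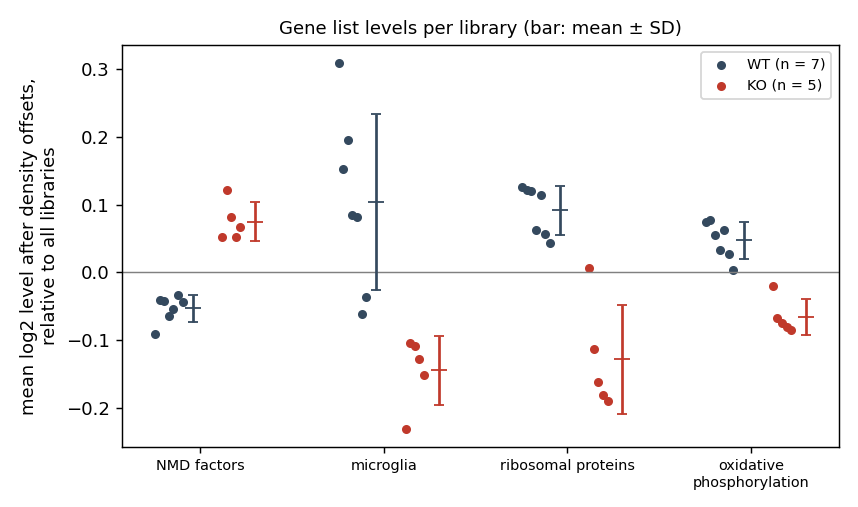
Mean log2 level of 4 gene lists in each library after density offsets, relative to the mean of all libraries (vertical axis). Points are the 7 WT and 5 KO mice and bars the group mean ± SD; NMD factors lie higher in all KO mice, and microglia, ribosomal protein and oxidative phosphorylation genes lower.

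Genes annotated with a transcript that NMD can target were also slightly higher. In 3869 tested genes with a stop codon over 50 nt upstream of the last exon junction, the median log2 fold change was 0.056, against 0.024 in the other 10405 (camera p = 0.0328; p = 0.00333 with an estimated correlation). Of these genes 21.3% were called higher and 12.5% lower, against 13.1% and 15.1% of the others. With density offsets the medians were 0.026 and -0.011, with a camera p of 0.00740 (1.69e-04 with an estimated correlation). The median of 0.026 lay above those of all 10000 random lists matched on exonic length and count density, 95% of which lay between -0.0090 and -0.00062, a comparison added after the data were seen. Leaving out KO 1 or WT 4 gave camera p values of 0.0588 and 0.0668, and leaving out both KO 2 and WT 4 gave 0.0686. It was 0.0698 with limma-voom sample weights and 0.0541 without the filter on low counts. In a permutation of the libraries over 100 splits, the real one included, 2 splits gave a camera p as small as the real one, and 1 with density offsets.

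Genes with transcripts already reported as NMD substrates changed in both directions. Counts were per gene, so a targeted transcript was not measured apart from other transcripts of its gene. Of 26 such genes tested, 4 rose and 7 fell (the same counts adjusted over the list alone). The list missed the threshold by camera (adjusted p = 0.308) and passed by fry, which asks whether a list's own genes move on balance one way (adjusted p = 0.0286). Snhg12, a snoRNA host gene, rose by a log2 fold change of 0.55 ± 0.06 (SE), while Hnrnpdl, Rps9 and Rpl12 fell by 0.29, 0.30 and 0.37 on the log2 scale. With density offsets 4 rose and 3 fell, and Rps9 did not pass, at -0.080 (adjusted p = 0.201). Rps9 and Rpl12 also belong to the list of cytosolic ribosomal proteins, in which 67 of 78 genes fell without offsets. The 23 snoRNA host genes had 3 higher and 3 lower members (3 and 3 adjusted over the list alone; camera adjusted p = 0.484), with Snhg12 higher and Eif4a2, Cct6a and Hspa8 lower, and with density offsets 2 were higher and 4 lower. The list for the exon junction complex, the protein mark that UPF3B binds, also held Upf2, which is in the list of NMD factors too. Of the 14 members of the complex list 2 rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.476). Casc3 and Upf2 were higher, at 0.23 ± 0.05 and 0.16 ± 0.05, and Rnps1 and Eif4a3 lower, at -0.16 ± 0.04 and -0.16 ± 0.05. With density offsets 2 rose and 2 fell; Casc3 passed, but Upf2, Rnps1 and Eif4a3 did not, at 0.14, -0.012 and -0.12 (adjusted p = 0.0563, 0.861 and 0.0957). Upf2 also missed the threshold with DESeq2 (adjusted p = 0.0554) and without KO 3, KO 4, KO 6, WT 1, WT 4 or WT 5 (adjusted p = 0.0736, 0.0811, 0.0539, 0.0520, 0.0507 and 0.0514).

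Splicing regulators that control themselves through poison exons were lower. Of 37 members 18 fell and 1 rose (21 and 1 adjusted over the list alone), including Hnrnpdl, Rbm3, a cold-inducible RNA-binding protein (-0.38 ± 0.05), Hnrnpk (-0.28 ± 0.04) and Tra2b (-0.23 ± 0.04). The camera adjusted p was 4.58e-06 (adjusted p = 0.579 with an estimated correlation). With density offsets 5 fell and 1 rose (camera adjusted p = 0.0403; 0.999 with an estimated correlation), and with the library total as a covariate the call was lost (adjusted p = 0.157).

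Several activity-regulated immediate early genes, which neurons switch on after stimulation, were lower. Of 39 tested 9 fell and 2 rose (9 and 3 adjusted over the list alone). Btg2 dropped from 65.0 ± 13.9 to 35.6 ± 7.25 CPM (log2 fold change -0.86 ± 0.15 SE), Cyr61 by a log2 fold change of -0.80 ± 0.10, Dusp1 of -0.39 ± 0.07 and Junb of -0.35 ± 0.06. The camera adjusted p of 0.0259 became 0.628 with an estimated correlation, 0.0946 with density offsets, 0.120 after cyclic loess, 0.0870 without KO 1, 0.112 without WT 4 and 0.153 without KO 2 and WT 4. All 4 genes still passed with density offsets, at -0.90 for Btg2, -0.89 for Cyr61, -0.33 for Dusp1 and -0.19 for Junb.

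Clock genes of the period family were higher. Of 19 circadian genes 5 rose and none fell (5 and 0 adjusted over the list alone), among them Per3 (74.9 ± 4.84 to 111 ± 3.35 CPM, log2 fold change 0.57 ± 0.05 SE), Per2 (0.61 ± 0.12), Per1 (0.36 ± 0.06) and Clock (0.19 ± 0.04). The list missed the threshold by camera (adjusted p = 0.308) and passed it with density offsets (adjusted p = 0.0270; 0.613 with an estimated correlation), where 6 rose, and with the library total as a covariate (adjusted p = 0.00108). Glucocorticoid-responsive genes went both ways, with 5 of 19 higher, such as Per1 and Map3k6, and 4 lower, such as the metallothioneins Mt1 and Mt2 (7 and 4 adjusted over the list alone; camera adjusted p = 0.439; fry adjusted p = 0.0122). With density offsets 2 were higher and 2 lower; Per1 passed, and Map3k6, Mt1 and Mt2 did not, at 0.31, -0.13 and -0.095 (adjusted p = 0.145, 0.0752 and 0.287).

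Heat shock genes were lower, with 10 of 18 falling and none rising (10 and 0 adjusted over the list alone; camera adjusted p = 3.56e-05; 0.320 with an estimated correlation). Dnaja1, Hspe1, Hsp90aa1 and Hspd1 had log2 fold changes between -0.31 and -0.18. With density offsets 4 fell and the list missed the threshold (adjusted p = 0.0823), as did Hsp90aa1 and Hspd1 (adjusted p = 0.0701 and 0.440). Of the 39 genes of the unfolded protein and integrated stress responses 4 rose, such as the amino acid sensor Eif2ak4 (0.39 ± 0.05), and 6 fell, such as Asns (-0.20 ± 0.04), with 4 and 6 adjusted over the list alone (camera adjusted p = 0.308; fry adjusted p = 0.0168). With density offsets 5 rose and 2 fell, and Asns did not pass, at -0.057 (adjusted p = 0.371).

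Genes of neurogenesis and neuronal growth changed singly and did not pass as lists. Among 24 markers of neural stem and progenitor cells 8 rose and 3 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.329). Mki67, a proliferation marker, rose by a log2 fold change of 0.53 ± 0.13 (SE) and Prom1 by 0.33 ± 0.09, while the transcription regulators Sox2 and Id4 fell, at -0.30 ± 0.06 and -0.36 ± 0.09. With density offsets 2 rose and 2 fell (camera adjusted p = 0.999); Sox2 and Id4 passed, and Mki67 and Prom1 did not, at 0.27 and 0.19 (adjusted p = 0.160 and 0.211). Of 32 genes of immature neurons and neurite outgrowth 1 rose, Dpysl3 (0.41 ± 0.08), and 6 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.353). The falls of Gap43 (-0.22 ± 0.04) and Tubb3 (-0.22 ± 0.04) were 0.0013 and 0.036 with density offsets, where 1 gene rose and 1 fell.

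Synaptic genes changed in both directions. Of 44 genes of excitatory synapses 6 rose and 8 fell (6 and 8 adjusted over the list alone; camera adjusted p = 0.329). The glutamate receptor subunits Grin2d (0.44 ± 0.09), Grin3a (0.35 ± 0.08) and Grik3 (0.31 ± 0.06) rose, and the scaffold Dlg4 fell (-0.26 ± 0.05). With density offsets 4 rose and 1 fell, with the list's direction up (camera adjusted p = 0.421), and Dlg4 was at -0.10. Of 23 GABA receptor and inhibitory synapse genes 7 fell, such as Gabbr1 (-0.21 ± 0.05), and 2 rose, such as Gabra2 (0.51 ± 0.12), with 11 and 2 adjusted over the list alone. That list was lower by camera (adjusted p = 0.0361; 0.628 with an estimated correlation), but its median of -0.10 turned to 0.038 with density offsets, where 3 members rose, none fell and Gabbr1 was at -0.0095 (adjusted p = 0.837). Leaving out KO 3, KO 4, WT 3, WT 4 or WT 6 gave adjusted p values of 0.0614, 0.0539, 0.0544, 0.0592 and 0.0584. Of 55 genes of X-linked intellectual disability, the class of disorder that UPF3B mutations cause in people, 7 rose and 9 fell (7 and 9 adjusted over the list alone; camera adjusted p = 0.616). Kdm5c and Pcdh19 rose (0.32 ± 0.05 and 0.35 ± 0.06), and Atp6ap2 and Lamp2 fell (-0.27 ± 0.04 and -0.22 ± 0.03). With density offsets 6 rose and 4 fell, with the list's direction up (camera adjusted p = 0.647), and Atp6ap2 was at -0.082.

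Among cell type markers, those of microglia, the resident macrophages of the brain, were lower. Of 20 genes 9 fell and none rose (13 and 0 adjusted over the list alone), with Fcrls going from 51.8 ± 7.13 to 32.3 ± 5.89 CPM (log2 fold change -0.67 ± 0.11 SE) and the purinergic receptor P2ry12 and Ctss each falling by 0.30 on the log2 scale. The camera adjusted p was 3.28e-06 (adjusted p = 0.544 with an estimated correlation), and with density offsets 8 fell (camera adjusted p = 6.46e-07; 0.613 with an estimated correlation). The mean microglial level ranged widely among WT mice, from -0.061 in WT 6 to 0.31 in WT 1 on the log2 scale, and all KO mice lay below, from -0.23 to -0.11.

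Astrocyte markers were lower, with 10 of 21 falling and none rising (12 and 0 adjusted over the list alone; camera adjusted p = 0.000101; 0.579 with an estimated correlation). Clu, Aldoc, Sox9 and Glul had log2 fold changes between -0.39 and -0.31. With density offsets 2 fell, Aldoc and Sox9 (camera adjusted p = 0.667), and with the library total as a covariate the adjusted p was 0.262. Of 25 oligodendrocyte and myelin genes 2 rose, Olig2 among them (0.24 ± 0.05), and 7 fell, such as Qdpr and Cnp (2 and 7 adjusted over the list alone; camera adjusted p = 0.0744). That list was lower without KO 2 (adjusted p = 0.0357), WT 1 (0.0437), WT 4 (0.0175) or both KO 2 and WT 4 (0.00657), and with sample weights (0.0167), but with density offsets 3 rose and none fell, with a median of 0.025 and the direction up (camera adjusted p = 0.647). Cnp and Qdpr were then at 0.058 and -0.077 (adjusted p = 0.248 and 0.101). With an estimated correlation the camera adjusted p of the oligodendrocyte and myelin list was 0.694, and 0.999 with density offsets. Of 14 genes of oligodendrocyte precursors 7 rose, such as Cspg4 (0.50 ± 0.09) and Gpr17 (0.41 ± 0.08), and Bcas1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.104; fry adjusted p = 0.0319). With density offsets 3 rose, Cspg4 and Gpr17 among them, and Bcas1 fell (-0.12).

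Vascular markers had more members higher than lower. Of 18 endothelial genes 7 rose, such as Vwf (0.68 ± 0.10), the glucose transporter Slc2a1 (0.28 ± 0.04) and Tek (0.38 ± 0.10), and 2 fell, including Bsg (8 and 2 adjusted over the list alone). That list missed the threshold by camera (adjusted p = 0.103; 0.0243 without KO 2 and 0.00348 with the library total as a covariate) and passed by fry (adjusted p = 0.0211). With an estimated correlation the camera adjusted p of the endothelial list was 0.628, and 0.891 with density offsets. With these offsets 2 endothelial genes rose, Vwf and Slc2a1. Tek and Bsg did not pass, at 0.22 and -0.061 (adjusted p = 0.196 and 0.147). Of 21 genes of pericytes, smooth muscle and meninges 5 rose, such as Col1a2 (0.53 ± 0.11) and Col1a1 (0.74 ± 0.19), and Ptgds fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.308; fry adjusted p = 0.0847). With density offsets Col1a2 passed, and Col1a1 and Ptgds did not, at 0.54 and -0.038 (adjusted p = 0.0697 and 0.464).

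Neuron type and dissection markers did not pass as lists. Camera called the direction of the X-linked disability, interneuron and choroid plexus lists down although their medians were above 0, and the means of the glutamate, NMD substrate, snoRNA host, excitatory neuron and interferon lists were above 0 against a median and a test below it. Excitatory neuron markers had 2 higher and 5 lower of 27 (2 and 5 adjusted over the list alone; camera adjusted p = 0.595), and the falls of Rgs4, Nrgn, Camk2a and Slc17a7, between -0.39 and -0.25, were -0.020, -0.11, -0.024 and 0.019 with density offsets, where 1 marker rose and none fell. Interneuron markers had 1 higher, Adarb2 (0.69 ± 0.09), and 4 lower of 22, such as Npy (-0.43 ± 0.08), Sst (-0.34 ± 0.06) and Cck (-0.39 ± 0.09), with 1 and 3 adjusted over the list alone (camera adjusted p = 0.595). With density offsets Adarb2 and Npy passed, and Sst and Cck did not, at -0.11 and -0.15 (adjusted p = 0.0682 and 0.114). Of 22 striatal genes 1 passed, Eya1, at 0.23 (adjusted p = 0.0472), and none did adjusted over the list alone (camera adjusted p = 0.813). Eya1 missed the threshold with DESeq2 (adjusted p = 0.132), with density offsets (0.662), without any 1 of the 5 KO mice (0.0541 to 0.119) and without WT 1, WT 2, WT 5, WT 6 or WT 7 (0.0743 to 0.0919). None of 13 olfactory bulb genes passed edgeR's test, over all genes or adjusted over the list alone (camera adjusted p = 0.967), though the list was lower with the library total as a covariate (adjusted p = 0.00578). The member Cdhr1, a cadherin of olfactory bulb output neurons singled out after its values were seen, lay at 65.2 CPM in KO 2, 62.1 in WT 4 and 49.4 in KO 4, against 6.42 to 10.9 in the other libraries. KO 2 also had the highest Slc17a6 (90.2 CPM) and Prlr (23.5 CPM). Without KO 2 and WT 4, 2166 genes were higher and 2189 lower, and microglia markers had a camera adjusted p of 5.42e-06. That fit kept KO 4, and no fit left out KO 2, KO 4 and WT 4 together. Of 17 hippocampal and thalamic genes 2 rose, Rgs16 and Lef1 (2 adjusted over the list alone; camera adjusted p = 0.308), and Lef1 did not pass with density offsets (adjusted p = 0.182). Of 7 choroid plexus genes 1 fell, Enpp2 (1 adjusted over the list alone; camera adjusted p = 0.813), which missed the threshold with density offsets (adjusted p = 0.725) and without KO 2, KO 3 or KO 6 (0.0536, 0.0507 and 0.0539). Of 23 interferon-stimulated genes 3 rose, Mx2, Irf9 and H2-D1, and 3 fell, such as B2m (3 and 2 adjusted over the list alone; camera adjusted p = 0.813). With density offsets Mx2 and B2m passed, and Irf9 and H2-D1 did not, at 0.26 and 0.27 (adjusted p = 0.0686 and 0.0768). None of the 3 tested blood cell genes passed; Alas2 had a log2 fold change of 0.36 (adjusted p = 0.138) and Ptprc of -0.12 (adjusted p = 0.462).

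Genes for cytosolic ribosomal proteins and for oxidative phosphorylation were lower almost throughout. Of 78 ribosomal protein genes 67 fell and 1 rose (67 and 1 adjusted over the list alone), with a median log2 fold change of -0.32; Rpl14 went from 72.4 ± 3.45 to 54.9 ± 4.63 CPM and Rpl6, Rpl32 and Rps3a1 had log2 fold changes of -0.37, -0.35 and -0.36. Of 80 nuclear genes for oxidative phosphorylation 74 fell and 3 rose (74 and 3 adjusted over the list alone), with a median of -0.28; Cox6c went from 39.9 ± 1.51 to 29.0 ± 1.11 CPM, and Ndufa12, Atp5h and Ndufb8 had log2 fold changes of -0.48, -0.38 and -0.30. The camera adjusted p values were 2.32e-26 and 1.74e-28, and each was 0.320 with an estimated correlation. With density offsets 50 of the ribosomal and 27 of the oxidative phosphorylation genes fell, with medians of -0.21 and -0.11 (camera adjusted p = 5.07e-19 and 7.24e-09; each 0.343 with an estimated correlation), and Rpl32 and Ndufb8 did not pass (adjusted p = 0.0565 and 0.311). KO 1, the shallowest KO library, had a mean ribosomal protein level of 0.0058 on the log2 scale against -0.19 to -0.11 in the other KO libraries and 0.043 to 0.13 in WT.

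Genes next to Upf3b on chromosome X held more lower calls than genes elsewhere, but not more calls in all. Of 28 tested genes within 10 Mb, 9 were called, and all 9 were lower. Calls in either direction made up 32.1%, against 29.6% of other genes (two-sided Fisher's exact test p = 0.836, odds ratio 1.12). Lower calls alone, tested after all 9 had been seen to be lower, made up 32.1% against 14.3% (two-sided Fisher's exact test p = 0.0134, odds ratio 2.83). With density offsets 7 of the 28 were called, again all lower (25% against 8.22%; Fisher's exact test p = 0.00650, odds ratio 3.72). All 9 lay within 2 Mb, where calls in either direction had an odds ratio of 1.78 (Fisher's exact test p = 0.230) and lower calls one of 4.49 (p = 0.00146). Within 20 Mb lower calls did not pass (Fisher's exact test p = 0.0678). Of all 28 genes, called or not, 17 had a log2 fold change below 0, with a median of -0.020 against 0.034 elsewhere (camera p = 0.00476; p = 0.0551 with an estimated correlation). In a permutation of the libraries over 100 splits, the real one included, 6 gave a camera p as small for these genes. Mcts1, a translation re-initiation factor, had a log2 fold change of -0.42 ± 0.06 (SE), Ndufa1 of -0.39 ± 0.08, C1galt1c1 of -0.31 ± 0.06 and Lamp2 of -0.22 ± 0.03, and those of Pgrmc1 (-0.25 ± 0.04) and Slc25a5 (-0.26 ± 0.04) became -0.026 and -0.045 with density offsets. The 13 mitochondrially encoded mRNAs were not analysed here. Y-linked Uty and Kdm5d were higher in KO (0.48 ± 0.06 and 0.43 ± 0.09), 2 of the 4 sex-linked genes tested (2 adjusted over the list alone). All 12 libraries carried Y-linked counts, with Ddx3y at 443 to 713.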

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

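Chosen after the results were seen were the tests of count levelling and GC content, of the density trend and flanking DNA for the largest fold changes, of variants shared by all KO mice, and of lower genes near Upf3b, as were all fits with density offsets and the counts of splits for single lists. The tests on matched lists, on library totals for ribosomal genes, on single KO mice and on other splits of the samples for the remaining results were written down before their results were seen.

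A single mouse stood far from its group in 4 of 56 groups tested, and chance marks about 1 in 20. These groups did not cover every gene reported here. Picked after their values were seen, Hspa8, Glul and Camk2a in KO 1 lay at 235, 366 and 746 CPM. The other KO mice lay at 173 to 178, 282 to 295 and 560 to 602 CPM. KO 1 was inside the WT range for each, so the falls of these genes rest on the other KO mice. Ttc39aos1 was at 33.6 CPM in KO 2, against 14.3 to 18.5 in the other KO mice, a gap of 0.785 of the group's range. Krt20 was at 5.76 CPM in KO 6, against 0.148 to 0.615 (0.917 of the range). 4931408D14Rik was at 3.68 CPM in KO 1, against 0.311 to 0.988 (0.799). Krt12 was at 45.9 CPM in KO 6, against 3.89 to 7.10 (0.924).

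Fold changes fell with count density, with a Spearman rho of -0.53 across genes, which are not independent replicates, and rose with exonic length (rho 0.292), a trend that density offsets left at 0.240 and whose cause was not tested. GC content is argued against, since its rho with the fold change was 0.0433. Counts that level off at high density in deeper libraries stay open: after removing group means, the slope of each library's counts on density had a Pearson r of -0.717 with the log2 library total over 12 libraries (permutation p = 0.0468, adjusted p = 0.0792 over 2 relations) and a Spearman rho of -0.566 (permutation p = 0.0685, adjusted p = 0.0795). Without the 2 libraries farthest from the median total r was -0.27, so the relation rests on them. Within groups, the median slope of log count on log library total ran from 1.53 in the lowest of 10 density bins to 0.63 in the highest. Densely counted genes thus followed the total less, though this slope rests on the same 12 libraries and was not tested. Depth and genotype cannot be told apart here because 4 of the 5 KO libraries were deeper than every WT library.

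The largest fold changes at single genes do not come from the density trend alone, since 23 of the 24 passed in the same direction with density offsets and the remaining gene, 4931408D14Rik, had no length for that fit. DNA flanking Upf3b is argued against as well, with 0 of the 24 within 10 Mb. Variants in the background of the KO mice may account for some, since 47 called genes past 2-fold had KO and WT mice that did not overlap, but this cannot be told apart from the genotype because the substrain and colony of the KO and WT mice are not given in the sources used here. Variants still segregating among KO mice are open too: at 26 genes 1 KO mouse lay in the WT range and the other 4 apart, against 17 genes with 1 WT mouse in the KO range, but 13 of the 26 were in KO 6 and 10 of the 17 in WT 4, which leaves 13 and 7 in the other libraries. Among the 26 were the neighbouring genes Krt12 and Krt20 on chromosome 11, at the WT level in KO 6, and Psmc3ip on the same chromosome, at the WT level in KO 4 (4.31 CPM, against at least 17.6).

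Ribosomal protein and oxidative phosphorylation genes stayed lower with density offsets, with medians of -0.21 and -0.11. Gene length and count density are argued against as the whole cause, since 0% of 10000 random lists matched on both lay as low (95% of them between -0.091 and -0.029 for the ribosomal list, and between -0.072 and -0.025 for the other). A ribosomal level that follows the library total stays open, with a group-centred r of -0.702 over 12 libraries (permutation p = 0.0792, adjusted p = 0.0792; rho -0.545, permutation p = 0.0795) that was -0.24 without the 2 libraries farthest from the median. An effect of the genotype on these genes is a hypothesis that the tests leave open.

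Chance alone is argued against for the number of genes, though 1 in 100 is the smallest share that 100 splits can give. Of these splits of the libraries into 5 and 7, the real one included, 1 gave as many as 4233. The highest other gave 3754. That other split set KO 2, KO 3, KO 4, KO 6 and WT 4, the 5 deepest libraries, against the rest. With density offsets 1 of 100 splits gave as many as 2350 genes, and the highest other, the same split, gave 496. The only other split drawn with 4 KO mice set KO 1, KO 2, KO 4, KO 6 and WT 5, the shallowest library, against the rest, and edgeR called 0 genes in it in either fit (1845 and 1757 at an unadjusted p under 0.05). Between these 2 splits the number of calls went with depth, but the mice exchanged differ too, so they do not settle how much of the real count comes from depth. Chance cannot be excluded for the number of lists, since 43 of 100 splits called as many as 9 and the highest other called 15. For NMD feature genes 2 of 100 splits gave a camera p as small as 0.0328 (smallest other 0.0307), and for NMD factors 1 of 100 gave one as small as 0.00556 (smallest other 0.0213). For the 28 genes within 10 Mb of Upf3b chance cannot be excluded, since 6 of 100 splits gave a camera p as small as 0.00476 (smallest other 1.02e-04), and 9 of 100 with density offsets. With density offsets 14 of 100 splits gave a camera p as small for microglia markers, so chance cannot be excluded for them. For ribosomal proteins 2 of 100 did, the real one and the split of the 5 deepest libraries. That split gave a smaller camera p, 1.03e-21 against 1.69e-20 in the real one.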

How the results depend on the processing

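Density offsets, cyclic loess, the library total as a covariate and the fits without KO 2 and WT 4 were chosen after seeing the data. So was the test of lower calls alone near Upf3b, and the others were chosen beforehand. Upf3b stayed lower in every setting (-3.92 to -3.64 without 1 library). Among settings chosen beforehand, at an adjusted p under 0.05 alone, the share of higher calls ran from 43.3% to 53.7%. The lowest was with the Wald test of DESeq2 (1676 higher, 2191 lower) and the highest with limma-voom sample weights (3070 higher, 2648 lower). Numbers of genes higher and lower ran from 1585 to 2420 and from 1544 to 2467 without 1 library. They were 527 and 72 with a log2 fold of at least 0.5 as well, 1175 and 1175 with density offsets, 1273 and 1101 with density offsets without KO 2 and WT 4, and 84 and 11 with the library total as a covariate, where 1866 genes had an unadjusted p under 0.05, against 5918. Lists called ran from 7 to 11 without 1 library and were 0 with an estimated correlation. For lists, 699 of the comparisons with an alternative kept direction and side of the threshold, 22 lost the call, 11 gained one and 48 reversed; for named genes 3483 kept both, 291 lost the call, 3 gained one and 19 reversed. The sex term was not run, since all libraries carried Y-linked counts and Xist was not analysed here. Depth limits genes of few counts. Apart from stricter thresholds and fewer libraries, the cause was not tested.

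The mouse numbers did not pair the samples: same-numbered deviations correlated at 0.142, -0.376, -0.0474, -0.0758 and 0.0381, and no mouse correlated best with its own number. With a replicate block 1129 genes were higher and 1186 lower, and endothelial markers were called by camera at the preset correlation (adjusted p = 0.0356).

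The difference of NMD feature genes was 0.032 (0.0309 to 0.0380 without 1 library); it missed the threshold at 0.0318 with sample weights, 0.0274 without the filter on low counts and 0.0316 without KO 2 and WT 4. The odds ratio near Upf3b (1.08 to 1.66 without 1 library) was 0.875 with a window of 20 Mb and 0 with the library total as a covariate, which decides nothing, since 0.186 calls were expected there. For lower calls alone it was 2.83 (2.59 to 3.62 without 1 library), 1.63 with 20 Mb, past the threshold no longer, and 0 with the library total (0.0216 expected).

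Among genes, log2 fold changes that reversed with density offsets were Cnp 0.058, Gap43 0.0013, Ppp1r1b 0.034, Slc17a7 0.019 and Tubb3 0.036, and without KO 2 and WT 4 too, Cnp 0.026, Ppp1r1b 0.058, Slc17a7 0.040 and Tubb3 0.024. With the library total they were Camk2a 0.018, Nrgn 0.020, Prlr -0.25, Ptprc 0.011, Slc17a6 -0.068 and Slc17a7 0.074. Prlr was -0.28 with cyclic loess, -0.041 with limma-voom and -0.56 with sample weights, and ran from -1.03, without KO 2, to 1.42 without 1 library.

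List directions are given as a signed camera z. With density offsets reversed values were 1.40 for GABA receptors, 0.950 for X-linked intellectual disability, 0.0042 for choroid plexus, 0.341 for excitatory neurons, 1.29 for glutamate receptors, 0.0784 for immature neurons, 0.101 for interneurons and 0.863 for oligodendrocytes. With density offsets without KO 2 and WT 4 they were 1.73 for GABA receptors, 1.24 for X-linked intellectual disability, 1.71 for excitatory neurons, 2.19 for glutamate receptors, -0.360 for hippocampus and thalamus, 0.268 for immature neurons and -0.427 for olfactory bulb. With the library total they were 0.124 for GABA receptors, 0.156 for X-linked intellectual disability, 1.16 for excitatory neurons, 2.15 for glutamate receptors, -0.292 for hippocampus and thalamus, -3.21 for olfactory bulb, 1.04 for snoRNA hosts and -1.86 for striatal neurons. Cyclic loess gave 0.730 for X-linked intellectual disability and 1.05 for glutamate receptors, and 1 surrogate variable -1.18 for olfactory bulb and -1.53 for striatal neurons. The replicate block gave 0.285 for choroid plexus and -0.214 for olfactory bulb. Choroid plexus was 0.00062 without the low-count filter, olfactory bulb -0.0116 with robust dispersion, and without KO 2 and WT 4 excitatory neurons were 0.281 and olfactory bulb -0.0460. Without 1 library z ran from -1.05 to 0.150 for choroid plexus, -1.33 to 0.0287 for excitatory neurons, -0.660 to 0.157 for interferon genes, -1.13 to 1.16 for olfactory bulb and -0.664 to 1.79 for striatal neurons.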

Other observations

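The 6 gene families and the single genes below were chosen after their values were seen. The p values of the families are unadjusted and, after that choice, only describe them. Histone genes were lower: 4 of 14 fell and none rose by edgeR's test (camera p = 0.00115; p = 0.113 with an estimated correlation), and with density offsets 7 fell, with a median of -0.60 (camera p = 1.16e-06; p = 0.0331 with an estimated correlation). Hist1h2bc, a core histone, had a log2 fold change of -0.67 ± 0.10 (SE), and the linker histone gene Hist1h1c of -0.60 ± 0.11. Of 77 mitochondrial ribosomal protein genes 18 fell and 1 rose, in both fits (camera p = 1.77e-06, and 7.81e-07 with density offsets; p = 0.221 and 0.201 with an estimated correlation). Of 38 proteasome genes 26 fell and 1 rose (camera p = 6.65e-10; p = 0.0976 with an estimated correlation), and with density offsets 7 fell and 1 rose (camera p = 0.00580; p = 0.361 with an estimated correlation). Axonemal dyneins, the motors of motile cilia, had 6 of 8 members higher (camera p = 0.00180; p = 0.129 with an estimated correlation), and 2 with density offsets (camera p = 0.0206; p = 0.120 with an estimated correlation). With density offsets and without KO 2 and WT 4, 1 of the 8 was higher and 1 lower. Zinc finger genes had 61 of 348 higher and 13 lower, but 22 higher and 33 lower with density offsets, where their median turned from 0.083 to -0.025. Protocadherins had 2 of 54 higher and 1 lower, and their median turned from 0.098 to -0.056 with density offsets.

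Several single genes differed by large amounts, in mice whose substrain is not given in the sources used here. Background variants can therefore not be told apart from the genotype at these genes. Nnt, which encodes a mitochondrial transhydrogenase, went from 34.2 ± 3.03 to 61.7 ± 6.53 CPM (SD; log2 fold change 0.77 with density offsets) and the long noncoding RNA Pvt1 from 34.8 ± 2.57 to 74.5 ± 4.39 CPM (1.12). Entpd4 went from 204.9 ± 14.5 to 114.1 ± 3.68 CPM (-0.74) and Fgfbp3 from 19.7 ± 2.30 to 11.5 ± 1.97 CPM (-0.91). Ide, which encodes an insulin-degrading protease and lies on chromosome 19 like Fgfbp3, had a log2 fold change of -0.62 ± 0.07 (SE), and of -0.61 with density offsets. Gt(ROSA)26Sor, the transcript of the Rosa26 locus, went from 24.9 ± 2.23 to 14.2 ± 3.13 CPM (-0.90). Ttr, a choroid plexus gene, was at 75.7 CPM in WT 5 and 39.7 CPM in KO 2, and as low as 0.373 CPM in WT 4.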
